A study of Mus musculus with 9 samples.

How the data were processed

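Total RNA depleted of ribosomal RNA was sequenced with strand information from 4T1 cells in 9 libraries, 3 each of WT and of the Nat10 knockout lines KO-c19 and KO-c43. Per the labels, the replicates of each condition are biological replicates, and no batch is named. The submitters' processing notes name cutadapt, STAR, Partek and mm10; versions, the read counter and the annotation are not given in the sources used here. The deposited values are a signal per gene, gene counts that the authors divided by 1 size factor per library. The median over genes of the ratio to the geometric mean was the same in all 9 libraries, as median-ratio scaling leaves it. Between 82.7% and 83.7% of low values (up to 20 reads) lay within 0.1 of a whole multiple of 1 step per library, and the others were fractions of a read, so whole reads were not recovered and count models were not run. The step gave the normalized counts per read. Gene coordinates in the table are not those of GRCm38: of 22292 identifiers matched to that annotation, 468 had the same start and 21989 the same length. Coordinates are therefore printed as the table gives them.

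The deposited scaling was kept. Values were transformed as log2(value + 1), and genes with at least 10 in at least 3 libraries were tested, which left 17579 of 22469. One limma fit (limma 3.58.1, statmod 1.5.0, data.table version 1.17.8, R 4.3.3) with an intensity trend and robust empirical Bayes held the means of the 3 groups. It gave KO-c19 against WT, KO-c43 against WT and KO-c43 against KO-c19, two-sided, with Benjamini-Hochberg adjustment over genes within each comparison and a threshold of 0.05. A gene changed the same way in both lines when it passed in both comparisons with the same sign. The overlap was set beside that of independent lists and beside 50 simulated draws. In these all 9 libraries, WT included, were drawn without change around the WT means. Both comparisons then shared the drawn WT group. Nat10 was also tested with an exact permutation test. The median residual SD was 0.09 on the log2 scale, and counting error and culture-to-culture spread were not separated.

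The gene lists, 28 in all, were written from textbook knowledge, and the comparisons, the tests and the rule for naming genes were set with them, before the data were examined. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 52 tests, and again with an estimated correlation and with fry. Fry asks whether the members of a list move one way on balance and does not compare them with other genes. Genes were named by a rule. Nat10, Ep300 and Crebbp were always named. The others were the 10 rising and 10 falling genes with the largest mean change over both lines, the 4 rising and 4 falling with the largest change in each line, the 5 higher and 5 lower between the lines, and up to 4 members of each list with the smallest adjusted p. All but the list members had libraries that did not overlap between groups, which chance gives 10% of genes with 3 against 3, and a higher group mean of at least 727. Predicted genes and pseudogenes were passed over for naming and kept in every count. Some genes that the rule names are not reported here.

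The alternatives were other pseudocounts, filters, scalings, empirical Bayes settings and list tests, only the groups compared, a fold threshold, the replicate number as a block, and leaving out each library. Scaling by totals and protein-coding genes alone were added after the data were seen. The limma test was run on simulated data, in which 17115 genes passed the filter and 67, 67 and 64 of them were changed by 0.5, 1 and 2 on the log2 scale, where it called 11 unchanged genes in KO-c19 against WT and 9 in KO-c43 against WT. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. DNA copy number, protein and acetylation were not analysed here.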

Results

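Total RNA depleted of ribosomal RNA was sequenced from 4T1 cells, a mouse mammary tumour line that spreads from the mammary gland to distant organs when grown in mice. The cells were either unedited (WT) or carried a knockout of Nat10, which encodes an acetyltransferase that modifies cytidines in ribosomal RNA, transfer RNA and other transcripts. The 2 knockout lines, KO-c19 and KO-c43, and WT were each grown as 3 biological replicates, giving 9 libraries. Each dish of 6 cm was seeded with 300000 cells and collected 48 h later. The deposited values are normalized read counts per gene for 22469 genes. The normalized totals ran from 45628576 to 50123222 per library. In each library 1 read stood for 0.822 to 1.11 normalized counts, as estimated from the spacing of the low values. Changes are given as differences of mean log2(normalized count + 1) with their standard errors from limma, and folds are on that scale, which understates the change of low genes. The replicates are separate cultures of the same line, so p-values measure the spread between cultures of 1 WT line and 2 knockout lines and not the spread between independently edited lines.

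Nat10 was measured first, since it checks the labels. Nat10 (ENSMUSG00000027185) lies on the minus strand of chromosome 2 at 103551601 to 103591615 in the coordinates of the deposited table, whose build the table does not name. The gene had 6432, 6501 and 6428 normalized counts in the WT libraries. KO-c19 had 1748, 1761 and 1710, and KO-c43 had 1724, 1748 and 1766. The means were 26.95% and 27.05% of WT. The change was −1.89 ± 0.037 (SE) on the log2 scale in both lines, with limma adjusted p = 1.78e-17 in KO-c19 and 1.26e-17 in KO-c43, and the lines did not differ detectably from each other (log2 difference 0.01 ± 0.037, limma adjusted p = 0.928). An exact permutation test of each line against WT (two-sided, 3 against 3) gave p = 0.1, the smallest value that its 20 divisions allow. The values are sums over the whole gene, so they do not show which exons the remaining reads came from.

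**Figure D1:**
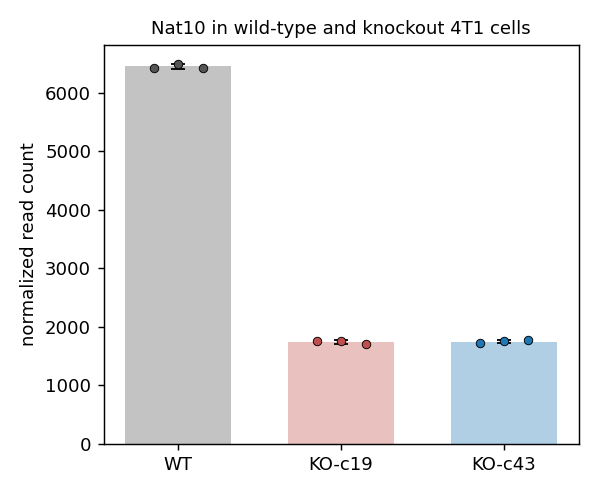
Normalized read count of Nat10 (vertical axis) in WT, KO-c19 and KO-c43. Points are the 3 libraries of each group, bars their mean and error bars the SD; all 6 knockout libraries lie between 1710 and 1766, below the WT libraries at 6428 to 6501.

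Ep300 and Crebbp encode the paralogous histone acetyltransferases p300 and CBP, which the title of the series names beside NAT10. Ep300 rose from 5733 ± 63.1 normalized counts in WT (SD, n = 3) to 8850 ± 463 in KO-c19 and 7457 ± 114 in KO-c43, by 0.63 ± 0.039 and 0.38 ± 0.039 on the log2 scale (limma adjusted p = 1.34e-10 and 1.24e-07). Crebbp rose by 0.18 ± 0.047 in KO-c19 (limma adjusted p = 0.00283). In KO-c43 its change of 0.03 ± 0.047 did not pass (limma adjusted p = 0.592), and the difference between the lines was −0.15 ± 0.047 (limma adjusted p = 0.0183). A list of 23 genes held acetyltransferases, bromodomain readers and coactivators, and also histone deacetylases, which have the opposite activity. Of these genes, 11 rose and 8 fell in KO-c19, and 11 rose and 4 fell in KO-c43. Kat6b, another histone acetyltransferase gene, rose 2.05-fold and 1.99-fold, and Ncoa1, a nuclear receptor coactivator gene, rose 1.81-fold and 1.55-fold. Brd7, a bromodomain gene of a chromatin remodelling complex, fell 1.54-fold and 1.65-fold. The list as a whole did not pass the camera test (adjusted p = 0.474 in KO-c19 and 0.201 in KO-c43).

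The first principal component of the 9 libraries held 65.8% of the variance and set WT apart from both knockout lines, and the second held 22.1% and set KO-c19 apart from KO-c43. Rn18s, the 18S ribosomal RNA left after depletion, took 3.14% ± 1.18 of normalized counts in WT (SD, n = 3), 1.09% ± 0.17 in KO-c19 and 1.74% ± 0.737 in KO-c43. Its share ranged from 2.06% to 4.40% among WT libraries, and KO-c43 overlapped them with 2.59% in replicate 3; these shares were not tested. Mitochondrially encoded genes took 2.84% ± 0.42, 4.19% ± 0.29 and 3.89% ± 0.24, and copies of 7SK RNA took 1.04% ± 0.053, 1.58% ± 0.053 and 1.39% ± 0.13.

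The comparison of KO-c19 with WT asks which transcripts differ between this knockout line and WT. Genes that were almost silent in WT and abundant in KO-c19 led the increases. Siglec15, a sialic acid-binding receptor gene, went from 6.14 ± 2.72 to 1188 ± 122 normalized counts (SD, n = 3), by 7.45 ± 0.232 on the log2 scale (limma adjusted p = 6.27e-11). Mgp, for the calcification inhibitor matrix Gla protein, went from 18 ± 7.68 to 2701 ± 196. Selp, for the adhesion receptor P-selectin, went from 24.1 ± 11.7 to 3283 ± 80.9, and Scara5, a scavenger receptor gene, from 15.6 ± 2.18 to 2091 ± 139. The decreases were led by genes of epithelial identity. Esrp1, a splicing regulator of epithelial cells, had 4373 ± 144 normalized counts in WT and was listed at 0 in all 3 KO-c19 libraries. Mal2, for a protein of apical transport, had 1806 ± 48.5 in WT and was also listed at 0 in all 3. The tight junction genes Cldn3 and Cldn7 had 3692 ± 288 and 2885 ± 174 in WT; in KO-c19 Cldn3 was listed at 0 in 2 libraries and at 2.23 in the other, and the highest Cldn7 value was 4.45. In all, 5761 genes rose and 6131 fell out of 17579 tested (limma, Benjamini-Hochberg adjusted p under 0.05), of which 1592 and 1127 changed at least 2-fold. Dividing each library by its total turned this split to 6848 rising and 5008 falling. In simulated counts at the depth of these libraries, the spread of each gene was capped and counting error was added to it. The simulation held far fewer changed genes than were called in the data. This comparison called 98.4% of genes changed by 2 on the log2 scale there. It called 74.6% of those changed by 1 and 47.8% of those changed by 0.5. These shares hold for that setting only, since the adjusted threshold is stricter when few genes change.

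The comparison of KO-c43 with WT puts the same question to the other line. Scara5 and Mgp were again among the largest increases, at 1069 ± 24.8 and 786 ± 26.0 normalized counts in KO-c43. With them stood Kctd12b, for a potassium channel tetramerization domain protein, which went from 118 ± 12.3 to 6440 ± 310 (5.76 ± 0.158 on the log2 scale, limma adjusted p = 2.46e-12), and Ube2ql1, for a ubiquitin-conjugating enzyme-like protein, which went from 25.3 ± 3.02 to 1059 ± 36.4. Among the largest decreases, Dsg2, for the desmosomal cadherin desmoglein 2, had 3144 ± 68.7 normalized counts in WT and was listed at 0 in all 3 KO-c43 libraries. Moxd1, for a monooxygenase-like protein, had 1571 ± 43.5 in WT and was likewise listed at 0 in all 3. Esrp1 was listed at 0 in 2 KO-c43 libraries and at 1.05 in the other, and no KO-c43 library had Cldn3 above 1.05. In all, 5712 genes rose and 5817 fell (limma adjusted p under 0.05), of which 1456 and 1087 changed at least 2-fold. Dividing each library by its total turned this split to 6214 rising and 5278 falling.

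Genes that changed the same way in both lines answer which changes the lines share in direction, though their size often differed between the lines. There were 4467 that rose in both and 4747 that fell in both, while 520 were called in opposite directions. With at least a 2-fold change in both, 1036 rose and 727 fell, and dividing each library by its total turned the split of all joint calls to 5142 rising and 3982 falling. Beyond Siglec15, Scara5, Mgp and Selp, the largest joint increases were in Gem, for a small GTPase that restrains calcium channels, which rose 68.8-fold in KO-c19 and 26.0-fold in KO-c43; Fer1l6, a ferlin family gene, at 62.2-fold and 20.9-fold; and Ace, for angiotensin-converting enzyme, at 61.6-fold and 18-fold. Nptx1, for neuronal pentraxin, rose 47.1-fold and 21.3-fold to 20850 ± 1483 and 9391 ± 171 normalized counts. Slpi, for a secreted leukocyte protease inhibitor, rose 45.1-fold and 21.3-fold, and Man1c1, for a Golgi mannosidase, rose 24.1-fold and 39.5-fold. The largest joint decreases again included junction, polarity and adhesion genes. Krt14, a keratin of basal epithelium, fell from 4960 ± 264 normalized counts to 22.2 ± 0.055 and 15.1 ± 1.36. Rab25, for a GTPase of apical recycling, fell from 1321 ± 57.2 to 5.38 ± 4.15 and 2.22 ± 1.02, and Itgb6, for an epithelial integrin subunit, from 1251 ± 121 to 0.742 ± 1.29 and 2.55 ± 0.924. Ap1m2, for an epithelial clathrin adaptor subunit, had 1044 ± 14.1 in WT; it was listed at 0 in all KO-c19 libraries and reached at most 1.05 in KO-c43. Mab21l4 had 970 ± 111 in WT and means of 0.675 and 2.20 in the lines.

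Both comparisons use the same WT libraries, which by itself makes their changes alike. In simulated draws with no changed gene and a shared drawn WT group, a mean of 0.1 genes was called in both with the same sign. With no gene changed almost none can be called, so this does not measure the overlap that shared controls give among many called genes. Lists of these lengths drawn independently would share 1872 rising and 2029 falling genes. Over all tested genes, which are not independent replicates, the log2 changes of the lines correlated with Pearson's r = 0.799 and Spearman's rho = 0.80, where simulated unchanged groups gave r = 0.50. The covariance was 0.901 against a simulated 0.0191, a difference of 0.882. With 3 WT libraries the controls could not be split into parts of at least 2, so part of the excess over independent lists may come from the shared controls.

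**Figure D2:**
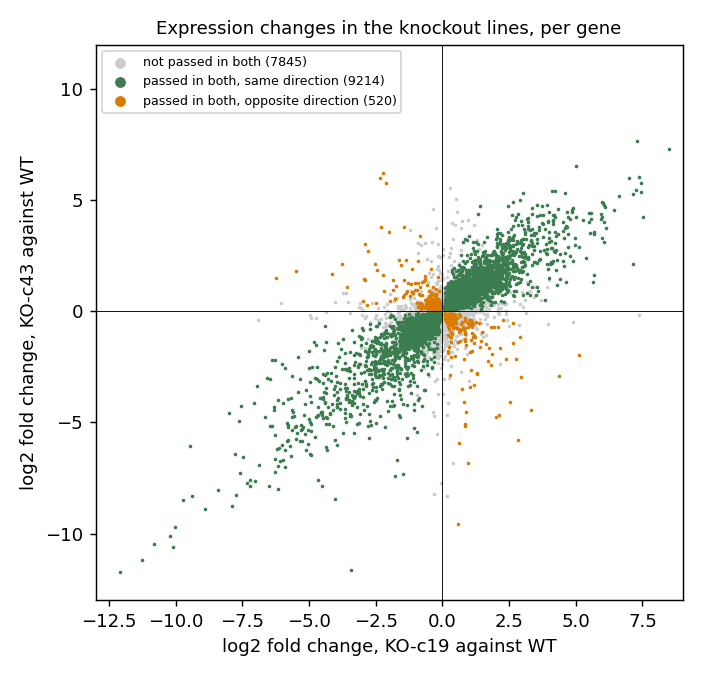
Log2 fold change against WT of each tested gene in KO-c19 (horizontal axis) and KO-c43 (vertical axis). Green points are the 9214 genes that passed in both lines with the same sign, orange points the 520 that passed with opposite signs, and grey points all others.

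The gene lists, written before the data were examined, were read in both lines. Each is given with its camera test at a preset correlation between genes of 0.01; no list passed with an estimated correlation after adjustment, and that adjusted p follows each call. Dividing each library by its total, an alternative to the deposited scaling, would raise the median log2 change of all tested genes to 0.10 in KO-c19 and 0.05 in KO-c43, so that list medians near 0 depend on the scaling. Among the lists described, only those for DNA replication, mitosis and hypoxia changed the sign of a median under TMM, total or quantile scaling, each in KO-c19 under total and quantile scaling. Members are counted by p-values adjusted over all genes tested. Adjusted over the list alone, the counts were the same except that in KO-c19 falling members were 9 for acetyltransferases, 13 for mitosis, 10 for TGF-beta targets and 5 for mesenchymal genes, and rising members 4 for snoRNAs and 5 for the ATF4 list. In KO-c43, adjusted over the list alone, falling members were 63 for ribosomal proteins, 33 for tRNA genes, 46 for histones, 12 for YAP/TEAD targets and 31 for epithelial markers, and rising members 12 for mesenchymal genes.

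Epithelial genes fell and several genes of mesenchymal cells rose. Of 34 epithelial markers tested, 28 fell and 4 rose in KO-c19 and 30 fell and 3 rose in KO-c43, with median log2 changes of −0.96 and −2.42 (camera adjusted p = 7.59e-07 and 1.13e-12; adjusted p = 0.278 and 0.223 with an estimated correlation). Cdh1, for the adherens junction protein E-cadherin, went from 26262 ± 327 normalized counts to 5797 ± 293 and 3731 ± 47.9, by −2.18 ± 0.039 and −2.82 ± 0.039 on the log2 scale (limma adjusted p = 4.25e-18 and 1.85e-19). St14, for the membrane protease matriptase, fell 3.02-fold and 13.6-fold. Of 19 tested genes linked to mesenchymal cells and the epithelial-mesenchymal transition, 13 rose and 4 fell in KO-c19 and 11 rose and 6 fell in KO-c43 (median 0.71 and 0.67, camera adjusted p = 0.00989 and 0.0195; adjusted p = 0.223 in both with an estimated correlation). The transcription factor genes Twist1 and Zeb2 rose 4.01-fold and 2.48-fold in KO-c19 and 4.15-fold and 3.11-fold in KO-c43. S100a4, for a calcium-binding protein of motile cells, rose 2.90-fold and 3.44-fold, whereas Nrp1, for a semaphorin and growth factor co-receptor, fell 4.63-fold and 3.60-fold. Outside the naming rule and chosen after their values were seen, Vim, for the intermediate filament vimentin, went from a mean of 37937 normalized counts to 78057 and 200832, and Epcam, an epithelial adhesion gene, from 6422 to 963 and 123.

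Matrix genes moved both ways. Of 33 tested collagens and matrix cross-linking enzymes, 18 rose and 13 fell in KO-c19, where the camera test did not pass (adjusted p = 0.125), and 20 rose and 9 fell in KO-c43 (camera adjusted p = 0.0167; adjusted p = 0.501 with an estimated correlation). Col6a1 rose 20.2-fold and 11.3-fold, Loxl3, for a lysyl oxidase, 9.24-fold and 18.5-fold, Col18a1 4.14-fold and 4.06-fold, and Col16a1 3.64-fold and 2.51-fold. Of 32 tested matrix proteases and their inhibitors, 19 rose and 10 fell in KO-c19 and 18 rose and 10 fell in KO-c43 (median 0.49 and 0.46, camera adjusted p = 0.0256 and 0.047; adjusted p = 0.278 and 0.319 with an estimated correlation), and the call ended in both lines under total scaling (camera adjusted p = 0.0511 and 0.056) and in KO-c43 also without its replicate 3 (0.0642), with the replicate number as a block (0.0526) and with a filter of at least 50 (0.0707). The members with the smallest p-values mostly went down: Adamts1 fell from 7444 ± 103 normalized counts to 122 ± 9.45 and 98.2 ± 10.2, Adam12 fell 12.6-fold and 27.5-fold, and Mmp9, for a gelatinase, fell 3.81-fold and 8.37-fold, while Ctsl, for cathepsin L, rose 2.99-fold and 2.12-fold.

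Sterol and fatty acid synthesis fell as a block. All 30 tested members fell in both lines, with median log2 changes of −1.71 and −1.82 (camera adjusted p = 1.05e-15 and 3.07e-17; adjusted p = 0.223 in both with an estimated correlation). Hmgcs1, for the synthase that makes HMG-CoA, went from 12580 ± 716 normalized counts to 2254 ± 64.1 and 2125 ± 43, by −2.48 ± 0.043 and −2.56 ± 0.043 on the log2 scale (limma adjusted p = 3.67e-18 and 2.34e-18). Idi1, for isopentenyl diphosphate isomerase, fell 5.84-fold and 6.6-fold, and Msmo1, for a sterol oxidase, 4.67-fold and 6.34-fold.

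**Figure D3:**
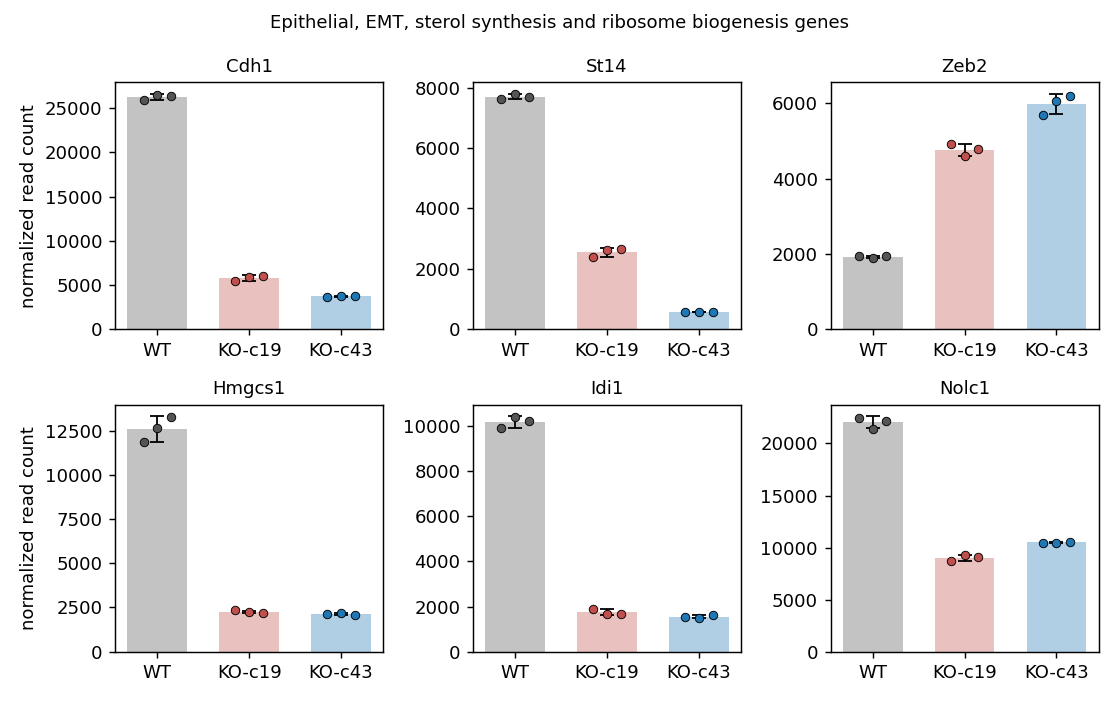
Normalized read counts (vertical axes) of 6 genes in WT, KO-c19 and KO-c43. Points are the 3 libraries per group, bars the mean and error bars the SD; Cdh1, St14, Hmgcs1, Idi1 and Nolc1 are lower and Zeb2 is higher in every knockout library than in every WT library.

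Genes for making ribosomes and transfer RNA fell together. In the list for rRNA processing and ribosome biogenesis, to which NAT10's own function in 18S rRNA belongs, 38 of 39 tested genes fell in each line and none rose (median −0.78 and −0.75, camera adjusted p = 9.36e-15 and 2.91e-15; adjusted p = 0.142 in both with an estimated correlation). Nolc1, for a nucleolar phosphoprotein, fell from 22026 ± 566 normalized counts to 9009 ± 262 and 10500 ± 63.2, Rrp12 fell 2.64-fold and 2.17-fold, Bysl 2.44-fold and 2.38-fold, and Bop1 2.08-fold and 2.17-fold. Of 74 cytosolic ribosomal protein genes, 53 fell and 3 rose in KO-c19 and 62 fell and none rose in KO-c43, by a median of −0.22 and −0.27 (camera adjusted p = 3.29e-05 and 4.9e-09; adjusted p = 0.236 and 0.223 with an estimated correlation). In KO-c19 total scaling left 35 falling and 7 rising with a median of −0.12. Rpl27 fell 1.69-fold and 1.66-fold, Rpl8 1.43-fold and 1.34-fold, Rpl4 1.32-fold and 1.41-fold and Rpl14 1.36-fold and 1.42-fold. These genes have many processed pseudogenes, so their counts may share reads with near-identical copies. Of 41 tested genes for tRNA transcription and modification, 36 fell and 4 rose in KO-c19 and 32 fell and 4 rose in KO-c43 (median −0.39 and −0.49, camera adjusted p = 2.15e-06 and 1.46e-06; adjusted p = 0.223 in both with an estimated correlation). Trmt6, for a tRNA methyltransferase subunit, fell 2.05-fold and 1.85-fold, Nsun2, for a tRNA cytosine methyltransferase, 1.82-fold and 1.48-fold, Mettl1, for a tRNA guanosine methyltransferase, 1.73-fold and 1.71-fold, and Thumpd1, whose product assists NAT10 in tRNA acetylation, 1.71-fold in both. Rn18s reads left after depletion took a lower share in every KO-c19 library than in every WT library, while KO-c43 overlapped WT. These shares were not tested, and they cannot tell the level of 18S rRNA from how well it was depleted. Of 15 snoRNA host genes, 10 fell and 3 rose in KO-c19 (camera adjusted p = 0.162) and 12 fell and 2 rose in KO-c43 (camera adjusted p = 0.0378; adjusted p = 0.501 with an estimated correlation); Snhg3 fell 1.77-fold and 1.96-fold, Snhg14 1.82-fold and 1.38-fold, Snhg16 1.31-fold and 1.32-fold, and Snhg12 1.29-fold and 1.30-fold. Of 23 tested snoRNAs and scaRNAs, 5 rose and 8 fell in KO-c19 and 7 rose and 7 fell in KO-c43, and the list passed in neither (camera adjusted p = 0.68 and 0.882); Scarna10, Scarna2 and Scarna13 rose 1.56-fold, 1.59-fold and 1.26-fold in KO-c19 and 1.65-fold, 1.18-fold and 1.23-fold in KO-c43, and Snora21 fell 2.32-fold and 2.13-fold.

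In the list for ATF4 and the amino acid response, 25 of 31 tested genes fell and 4 rose in KO-c19 and 22 fell and 5 rose in KO-c43 (median −0.62 and −0.36, camera adjusted p = 4.82e-06 and 0.000374; adjusted p = 0.278 and 0.413 with an estimated correlation). Mthfd2, for a mitochondrial folate enzyme, fell 4.90-fold and 2.77-fold, Aars, for alanyl-tRNA synthetase, 2.41-fold and 1.90-fold, Slc7a5, for a large neutral amino acid transporter, 2.00-fold and 2.01-fold, and Atf4 itself 1.87-fold and 1.66-fold. The 24 genes of the unfolded protein response split, with 10 rising and 9 falling in KO-c19 and 11 rising and 11 falling in KO-c43 (camera adjusted p = 0.554 and 0.662). Xbp1, Ern1 and Dnajb9, which belong to the IRE1 branch, rose 1.67-fold, 1.60-fold and 2.08-fold in KO-c19 and 1.72-fold, 1.36-fold and 1.53-fold in KO-c43, whereas the chaperone gene Dnajb11 fell 1.72-fold and 1.71-fold. Of 27 tested hypoxia and glycolysis genes, 11 rose and 8 fell in KO-c19 (camera adjusted p = 0.456) and 14 rose and 5 fell in KO-c43 (camera adjusted p = 0.041; adjusted p = 0.538 with an estimated correlation). Egln3, for an oxygen sensor, rose 4.33-fold and 3.63-fold, Vegfa 2.37-fold and 2.02-fold, Pdk1, for a pyruvate dehydrogenase kinase, 1.94-fold and 2.73-fold, and Mxi1 1.76-fold and 2.04-fold. For this list the mean log2 change was −0.26 and −0.13, opposite in sign to the camera direction in both lines, and the median was −0.02 and 0.16. The calls for hypoxia and for snoRNA host genes in KO-c43 ended without WT replicate 1 (camera adjusted p = 0.0658 and 0.0831), and that for snoRNA host genes also with a filter of at least 50 (0.0744).

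Of 21 tested YAP/TEAD targets, 15 fell and 5 rose in KO-c19 (median −1.25, camera adjusted p = 0.00049; adjusted p = 0.278 with an estimated correlation), and 11 fell and 9 rose in KO-c43 (median −0.18, camera adjusted p = 0.371). Ccn2, for connective tissue growth factor, fell from 11510 ± 393 normalized counts to 735 ± 8.56 and 2424 ± 102, Ccn1 fell 6.24-fold and 3.51-fold, F3, for tissue factor, 3.89-fold and 6.33-fold, and Wwc1 2.19-fold and 1.90-fold. Of 21 TGF-beta targets, 11 rose and 9 fell in KO-c19 and 12 rose and 8 fell in KO-c43 (camera adjusted p = 0.504 and 0.352). Their median was positive, at 0.53 and 0.35, and their mean negative, at −0.12 and −0.09, with some members falling far: Pmepa1 fell 7.54-fold and 5.45-fold and Bhlhe40 6.96-fold and 3.83-fold, while Ltbp1, for a latent TGF-beta binding protein, rose 1.94-fold and 2.10-fold. Of 31 immediate early and AP-1 genes, 17 rose and 10 fell in KO-c19 and 16 rose and 13 fell in KO-c43 (camera adjusted p = 0.0792 and 0.299). Egr3 rose from 90.1 ± 8.89 normalized counts to 2625 ± 211 and 2036 ± 45.1, and the feedback inhibitors of ERK signalling Spry4, Spry2 and Dusp6 rose 3.69-fold, 1.77-fold and 2.14-fold in KO-c19 and 2.76-fold, 1.91-fold and 2.64-fold in KO-c43. Of 20 tested p53 targets, 10 fell and 5 rose in KO-c19 and 12 fell and 7 rose in KO-c43 (camera adjusted p = 0.223 and 0.101). Cdkn1a, for the cell cycle inhibitor p21, rose 3.55-fold and 1.88-fold, whereas Plk2 fell 6.38-fold and 2.87-fold, Perp, for a desmosomal protein, 2.17-fold and 4.47-fold, and Aen 2.13-fold and 2.26-fold.

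Genes of the interferon, class I antigen presentation and NF-kappaB lists were mostly lower. Of 32 tested interferon-stimulated genes, 25 fell and 2 rose in KO-c19 and 18 fell and 6 rose in KO-c43 (median −0.61 and −0.44, camera adjusted p = 0.000966 and 0.0348; adjusted p = 0.236 and 0.393 with an estimated correlation), and the KO-c43 call ended with a filter of at least 50 (camera adjusted p = 0.0964). Ifih1 and Ddx58, for the RNA sensors MDA5 and RIG-I, fell 4.53-fold and 1.55-fold in KO-c19 and 5.01-fold and 1.73-fold in KO-c43; Bst2, for tetherin, fell 2.15-fold and 2.67-fold, and Ifi27 rose 1.77-fold and 2.39-fold. Of 20 genes for class I antigen presentation, 12 fell in each line and 5 and 3 rose (camera adjusted p = 0.153 in KO-c19 and 0.0256 in KO-c43; adjusted p = 0.278 in KO-c43 with an estimated correlation), and the KO-c43 call ended with a filter of at least 50 (camera adjusted p = 0.0625). H2-K1 fell 1.73-fold and 1.71-fold, Tapbp, for tapasin, 1.54-fold and 1.37-fold, Psmb10, for an immunoproteasome subunit, 1.45-fold and 1.42-fold, and H2-Q6, which has close paralogues that could share its reads, 2.10-fold and 3.08-fold. Of 29 tested NF-kappaB targets, cytokines and chemokines, 19 fell and 6 rose in KO-c19 and 20 fell and 8 rose in KO-c43 (median −0.55 and −0.70, camera adjusted p = 0.00806 and 0.00989; adjusted p = 0.278 in both with an estimated correlation). Cxcl16 fell from 6411 ± 99.8 normalized counts to 1574 ± 94.0 and 286 ± 18.3 and Il23a fell 3.11-fold and 4.15-fold, whereas Il11 rose 14.5-fold and 13.2-fold and Tnfaip2 rose 2.62-fold and 4.34-fold.

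Cell cycle genes changed little and in both directions. Of 36 DNA replication and E2F target genes, 10 rose and 15 fell in KO-c19 and 12 rose and 12 fell in KO-c43 (camera adjusted p = 0.43 and 0.68), and scaling by totals turned the KO-c19 split to 14 rising and 11 falling. Mcm2, Mcm5 and Orc1, for factors of replication licensing, fell 1.66-fold, 1.28-fold and 1.45-fold in KO-c19 and 1.28-fold, 1.41-fold and 1.53-fold in KO-c43, while E2f1 rose 1.33-fold and 1.48-fold. Of 29 mitosis genes, 14 fell in each line and 3 and 7 rose (camera adjusted p = 0.178 and 0.426), and scaling by totals left 9 falling and 8 rising in KO-c19 and 11 falling and 10 rising in KO-c43 and turned the KO-c19 median from −0.08 to 0.02. Aurka and Plk1, for mitotic kinases, fell 1.38-fold and 1.33-fold in KO-c19 and 1.40-fold and 1.32-fold in KO-c43, Bub1b 1.18-fold and 1.19-fold, and Kif20a rose 1.14-fold and 1.23-fold. Replication-dependent histones were lower, with 41 of 62 tested genes falling and 2 rising in KO-c19 and 45 falling and 3 rising in KO-c43 (median −0.28 and −0.27, camera adjusted p = 3.32e-05 and 6.58e-06; adjusted p = 0.512 and 0.503 with an estimated correlation), and the KO-c19 median was −0.18 under total scaling. H3c4 fell 2.11-fold and 1.87-fold, H4c2 1.43-fold and 1.39-fold, H2ac4 1.5-fold and 1.42-fold, and H2bc3 1.48-fold and 1.59-fold; these genes are near-identical to one another, so reads may be divided between copies. Of 13 mitochondrially encoded mRNAs, 11 rose in each line and none fell (median 0.50 and 0.52, camera adjusted p = 0.00192 and 0.00194; adjusted p = 0.501 in both with an estimated correlation), along with the larger mitochondrial share of reads given above. mt-Co1 rose 1.42-fold and 1.38-fold, mt-Nd2 1.60-fold and 1.57-fold, mt-Co2 1.49-fold and 1.41-fold, and mt-Co3 1.42-fold and 1.52-fold.

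**Figure D4:**
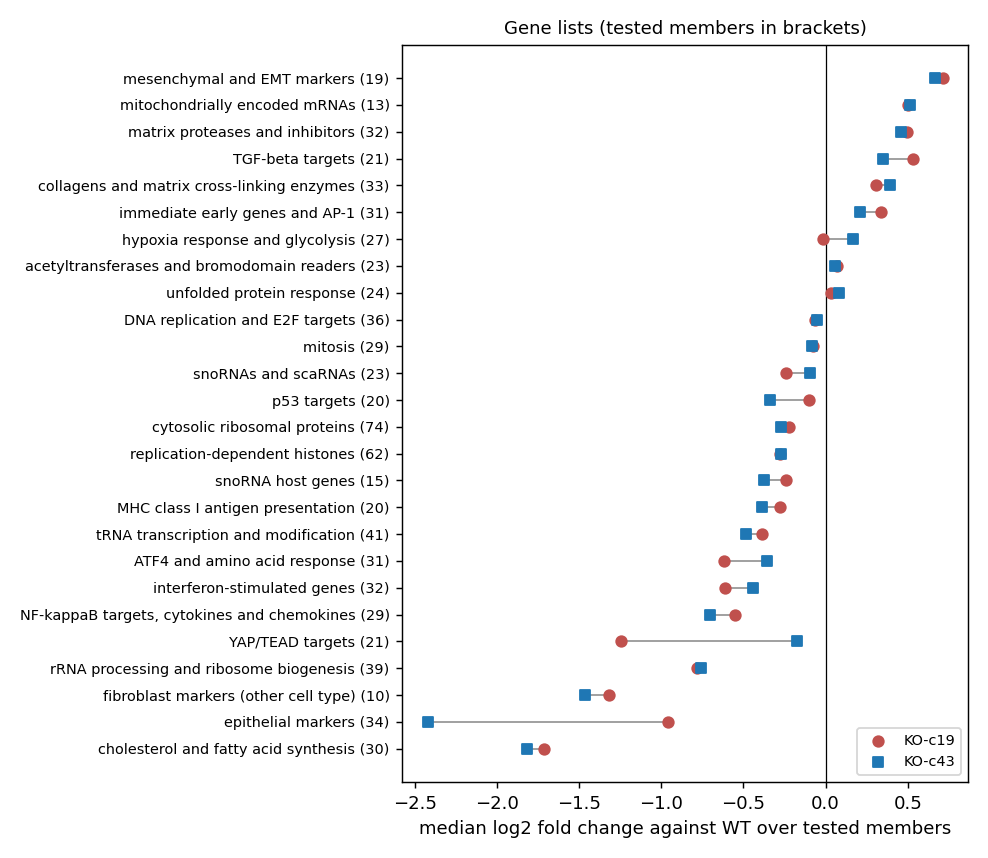
Median log2 fold change against WT (horizontal axis) over the tested members of each gene list with at least 5 of them, for KO-c19 (circles) and KO-c43 (squares). Cholesterol and fatty acid synthesis is lowest in KO-c19 at −1.71 and epithelial markers are lowest in KO-c43 at −2.42; mesenchymal markers are highest in both.

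Markers of cell types that a tumour culture could carry over moved both ways, and most tested fibroblast markers fell. Of the immune markers 4 were tested: Csf1r fell from 293 ± 14.1 normalized counts to 15 ± 3.07 and 12.6 ± 9.17; Cx3cr1 had 21.5 ± 2.51 in WT, 49.9 ± 7.6 in KO-c19 and 31.0 ± 1.42 in KO-c43; Cd14 had 388 ± 19.7, 302 ± 21.3 and 404 ± 28.2; and Cd68 had 182 ± 28.3, 280 ± 36.1 and 192 ± 19.8. Of the endothelial markers 4 were tested: Eng fell 1.30-fold and 1.40-fold, Flt1 rose 1.29-fold and 1.15-fold, Egfl7 had 467 ± 53.5, 420 ± 14.2 and 403 ± 21.8, and Pecam1 stayed at or below 17.2 in every library. Of 10 tested fibroblast markers, which mesenchymal tumour cells also express, 3 rose and 7 fell in KO-c19 and 2 rose and 8 fell in KO-c43 (camera adjusted p = 0.211 and 0.0698). The list passed in KO-c43 with a pseudocount of 8, under total scaling and without KO-c19 replicate 3 (camera adjusted p = 0.0375, 0.0476 and 0.0494). Postn, for periostin, had 192 ± 10.3 in WT and at most 1.11 in any knockout library, Gsn fell 1.47-fold and 2.39-fold, Pdgfra rose 3.17-fold and 1.64-fold, and Fbln1 had 80.3 ± 11.8 in WT, 579 ± 56.0 in KO-c19 and 0.698 ± 1.21 in KO-c43.

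The comparison of KO-c43 with KO-c19 asks where lines with the same disrupted gene differ. Kctd12b stood at 27.0 ± 7.12 normalized counts in KO-c19 and 6440 ± 310 in KO-c43, a log2 difference of 7.88 ± 0.158 (limma adjusted p = 5.21e-13). Mgat3, for a glycosyltransferase that bisects N-glycans, was 60.2-fold higher in KO-c43, Miga1, for a mitochondrial fusion factor, 28.3-fold, Cavin2, for a caveolar coat protein, 15.4-fold, and Vcam1, for a vascular adhesion receptor, 9.63-fold. Bcl11a, for a zinc finger repressor, had 753 ± 39.7 in WT and 1128 ± 27.2 in KO-c19 and was listed at 0 in all 3 KO-c43 libraries. Megf6 was 10.03-fold lower in KO-c43 than in KO-c19, Plat, for tissue plasminogen activator, 9.29-fold, Epn3, for an epsin of endocytosis, 8.75-fold, and Acap1, for an Arf GTPase-activating protein, 8.51-fold. In all, 3717 genes were higher and 3211 lower in KO-c43 (limma adjusted p under 0.05), of which 449 and 606 differed at least 2-fold. Dividing each library by its total turned this split to 2955 higher and 4314 lower, so the balance of the directions rests on the scaling.

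Several gene lists differed between the lines. YAP/TEAD targets were higher in KO-c43, with 17 of 21 higher and 3 lower and a median difference of 0.52 (camera adjusted p = 5.78e-08; adjusted p = 0.496 with an estimated correlation). Epithelial markers were lower, with 21 of 34 lower and 2 higher and a median of −0.49 (camera adjusted p = 1.12e-07; adjusted p = 0.529 with an estimated correlation). Genes of the ATF4 list were higher by a median of 0.18, with 20 of 31 higher and 3 lower (camera adjusted p = 2.94e-05; adjusted p = 0.529 with an estimated correlation). Changes of gene expression also followed chromosomes: among protein-coding genes above the naming level, the median difference between the lines was 0.37 on chromosome 13, 0.32 on chromosome 6 and 0.29 on chromosome 19, and between −0.04 and 0.06 on every other chromosome. These medians cover whole chromosomes, and stretches of some other chromosomes also differed, as given below.

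**Figure D5:**
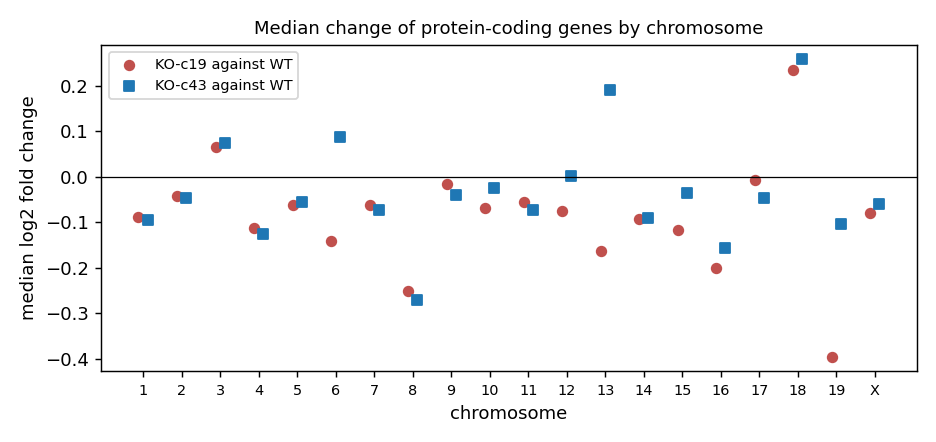
Median log2 fold change against WT (vertical axis) of protein-coding genes above the naming level on each chromosome (horizontal axis), for KO-c19 (circles) and KO-c43 (squares). The lines lie apart on chromosomes 6, 13 and 19, where the medians are −0.14, −0.16 and −0.40 in KO-c19 and 0.09, 0.19 and −0.10 in KO-c43.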

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

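The tests chosen only after the result was seen were those of neighbouring genes, library scaling and subpopulations for the epithelial genes, of unedited cells for Nat10, of the number of reads for the difference between the lines (in place of a test by gene level, whose outcome the smaller error of abundant genes largely fixed), and the view of the genes around Nat10.

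The results here came up because expression differed between KO-c19 and KO-c43 in limma's test of the difference itself (Benjamini-Hochberg adjusted p under 0.05). This test cannot tell differing effects of the knockout from other differences between the lines. There were 520 genes called in opposite directions against WT. Of 144 named genes, 96 differed between the lines, 32 of them at least 2-fold, and 7 went in opposite directions. Over all 17579 tested genes, 6928 differed, 1055 of them at least 2-fold. The naming rule took some genes by this same test and others by large changes, so the counts of named genes are partly set by it. Of the genes with the largest joint increases, these rose less in KO-c43, with log2 differences of −1.69 for Siglec15, −1.78 for Mgp, −1.83 for Selp, −1.40 for Gem, −1.57 for Fer1l6, −1.78 for Ace, −1.15 for Nptx1 and −1.08 for Slpi. Higher in KO-c43 were Kctd12b by 7.88, Mgat3 by 5.91, Miga1 by 4.82, Cavin2 by 3.95, Vcam1 by 3.27, Ube2ql1 by 2.34, Ccn2 by 1.72, Plk2 by 1.15 and Loxl3 by 1.00. Lower in KO-c43 were Megf6 (−3.33), Plat (−3.22), Epn3 (−3.13), Acap1 (−3.09), Cxcl16 (−2.45), St14 (−2.17), Mmp9 (−1.135), Adam12 (−1.13) and Perp (−1.04). Where 1 line was near 0, only levels are given: Dsg2 at 291, Bcl11a at 1128, Fbln1 at 579 and Pecam1 at 12.4 normalized counts in KO-c19. Itgb6 and Mab21l4 were near 0 in both lines, with means of 0.742 and 0.675 in KO-c19 and 2.55 and 2.20 in KO-c43. Their libraries overlapped between the lines, though both genes are among the 32 counted above. The other 64 named genes differed by 0.09 to 0.98 on the log2 scale. By camera, the lists that differed had median log2 differences of 0.52 for YAP/TEAD targets, −0.49 for epithelial markers, 0.18 for the ATF4 list, −0.17 for cholesterol and fatty acid synthesis, 0.12 for hypoxia and −0.0938 for ribosomal proteins, and none passed with an estimated correlation (adjusted p = 0.496 to 0.844).

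For each pair of groups, the 10 splits of the 6 libraries are too few for a share under 0.05. In fits on those 6 libraries the real splits gave 11749 genes for KO-c19 against WT, 11813 for KO-c43 against WT and 6608 between the lines, where the highest of the other splits gave 0; the real split was the 1 split with so many. For genes changed the same way in both lines, 1 of 100 splits of the 9 libraries gave as many as the real 9214. That 1 was the real split itself. The highest other split gave 7874. Splits that place WT and knockout libraries in the same group widen its spread, so few genes can be called in them. The libraries of a group are cultures of 1 line, so the splits cannot weigh chance differences between lines.

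The loss of epithelial genes was weighed first, with 27 of 34 tested epithelial genes falling in both lines. Deletion of neighbouring stretches is argued against as the whole cause: the 47 nearest tested genes beside those members, on 15 chromosomes, had a median log2 change of −0.0573 (95% bootstrap interval −0.28 to 0.19), where the members had −2.50. An earlier form of that test counted 2 of 30 genes lost in both lines with a lost neighbour. Library scaling is argued against too, since the least negative median of the list over 3 scalings and both lines was −0.86. A change of subpopulation while the lines were derived may explain the same 27 losses and cannot be told apart from an effect of Nat10 loss, because no derived line with intact Nat10 is among the libraries.

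Nat10 remained at 26.95% and 27.05% of WT in the lines. If the remaining reads came from unedited cells like WT mixed into each line, no gene could fall far below that share of WT. Yet 37 genes above the naming level lay under 13.5% of WT, below the Nat10 share, in both lines, 49 in KO-c19 and 61 in KO-c43. This argues against cells like WT as the source of all remaining reads. Unedited cells that had themselves lost such genes could not be seen by this test. Transcripts of the edited gene that are still made and counted may remain, and which exons the reads cover was not analysed here.

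For the 6928 genes that differ between the lines, the number of reads per library is argued against, since the mean estimated reads differed by 3.52% and all 3 KO-c43 libraries lay within the range of the KO-c19 libraries. Copy number of chromosome blocks was examined among 8156 protein-coding genes above the naming level only. Shifted blocks were stretches where the running median difference of 51 neighbouring genes went beyond shuffled gene orders. Of the genes called different, 22.6% (977 of 4332, not of all 6928) lay in shifted blocks with the sign of the block. These blocks held 14% of the genes examined. The 22.6% lay between the bounds of 10% and 50% set for the test. Blocks and calls came from the same differences between the lines, so genes in a block tend to be called with its sign by construction. The part that copy number may account for therefore cannot be read from this test and stays open without DNA. The longest blocks were higher in KO-c43, with 307 genes on chromosome 19 (median 0.29), 277 on chromosome 6 (0.38) and 252 on chromosome 13 (0.40). Against WT, their medians in that order were −0.395, −0.305 and −0.108 in KO-c19 and −0.103, 0.0847 and 0.262 in KO-c43. On chromosomes 19 and 6, KO-c19 thus lay further from WT than KO-c43 did. Shorter blocks were also higher on chromosomes 15 (84 genes, median 0.27), 12 (70 genes, 0.28) and 2 (46 genes, 0.33). A block of 31 genes on chromosome 9 was lower (−0.30). On chromosome 2, 29 of 30 genes from Ptprj to Api5 were lower in KO-c43 (median −0.47), within a block of 38 genes (median −0.40) that reaches 103.3 Mb, next to Nat10. Among 19 genes around Nat10 from Traf6 to Arl14ep, which overlap the end of that block, 6 were lower and 4 higher in KO-c43 (median 0.01), with medians of −0.39 and −0.35 against WT.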

How the results depend on the processing

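The tests chosen only after the data were seen were total scaling and protein-coding genes alone. The counts of changed genes kept within 1.5 times under every alternative except a threshold of at least 2-fold, which left 2719 genes in KO-c19, 2543 in KO-c43, 1763 the same way in both and 1055 between the lines, by its own construction. Leaving out each library gave 11199 to 11898, 10877 to 11908, 8697 to 9214 and 5960 to 7616 genes, and Nat10 at 26.93% to 27.13% of WT. With the replicate number as a block the counts were 11774, 11455, 9148 and 6799; the numbers do not pair the samples, since none of 9 pairs with the same number correlated above 0.1 (r −0.09 to 0.08) and 2 of 9 libraries were closest to their own number. Median-of-ratios scaling moves nothing here and says nothing on stability. Total scaling moved the median of all genes by 0.10 in KO-c19 and 0.05 in KO-c43 and turned the split between the lines to 2955 higher and 4314 lower. Of 5756 results for named genes, 5738 kept direction and side of the threshold, 14 lost the call and 4 gained it. Lost calls were Fbln1 in KO-c19 with a pseudocount of 0.1 (log2 2.85, limma adjusted p = 0.0692) and Pecam1, Egfl7 and Cx3cr1 in KO-c43. Of 1040 list results, 976 kept both, 39 lost the call (29 of them with an estimated correlation), 23 gained it (19 with fry) and 2 reversed: fry gave TGF-beta targets the other direction in KO-c19 (adjusted p = 0.000745) and KO-c43 (0.016), and the cause was not tested. In KO-c43 a filter of at least 50 ended the calls of snoRNA host genes, interferon-stimulated genes, class I antigen presentation and matrix proteases (camera adjusted p = 0.0744, 0.0964, 0.0625 and 0.0707), and matrix proteases also lost the call under total scaling (0.056; 0.0511 in KO-c19), with the block (0.0526) and without KO-c43 replicate 3 (0.0642); the cause was not tested. Calls gained other than with fry were those of fibroblast markers in KO-c43, given above, and of immediate early genes in KO-c19 without its replicate 1 (camera adjusted p = 0.0437). The planned edgeR and DESeq2 alternatives were not run because whole reads were not recovered.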

Other observations

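The families of genes named by symbol were chosen for testing only after the data were seen; the test of LXR targets was written before its result.

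Among 134 symbol families of at least 10 tested members, those named for mitochondrial ribosomes, translation factors and the proteasome fell in both lines. These directions held under total scaling. Of 49 Mrpl genes, for the large subunit of the mitochondrial ribosome, 44 fell in KO-c19 and 45 in KO-c43 (median log2 change −0.51 and −0.47, camera adjusted p = 3.19e-09 and 9.58e-10; adjusted p = 0.155 in both with an estimated correlation). The 54 Eif genes were grouped by symbol alone, so beside initiation factors they can include genes for proteins that act on those factors. Of these 54, 48 fell in KO-c19 and 45 in KO-c43, with medians of −0.43 and −0.46. Their camera adjusted p was 1.76e-09 and 3.54e-09, and 0.155 in both with an estimated correlation. Of 14 Psmd genes, for the proteasome regulatory particle, 14 and 13 fell (camera adjusted p = 5.39e-05 and 7.51e-05; adjusted p = 0.155 in both with an estimated correlation). All 11 Utp genes, for the small subunit processome, fell in both (camera adjusted p = 5.79e-05 and 1e-04; adjusted p = 0.298 and 0.309 with an estimated correlation). Among 329 Zfp genes, for zinc finger proteins, 146 rose and 73 fell in KO-c19 and 163 rose and 57 fell in KO-c43 (camera adjusted p = 0.0317 and 0.00557; adjusted p = 0.64 and 0.598 with an estimated correlation).

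An excess of sterols might lower cholesterol synthesis and, where LXR senses it, would raise LXR targets. Of 6 tested LXR targets, 2 rose in both lines, which lies between the bounds set for the test and leaves it open. Abca1 was listed at 0 in all WT libraries and rose by 3.96 ± 0.41 and 4.03 ± 0.41 on the log2 scale, so it stayed low in the lines. Abcg1 rose by 2.48 ± 0.2 and 2.69 ± 0.2 from 25.7 normalized counts in WT. Mylip changed by −0.31 and −0.46, Lpcat3 by −1.01 and −0.66, Nr1h3, for LXR alpha itself, by −1.16 and −1.12, and Plin2 by −1.51 and −1.54.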
